A study of Mus musculus with 6 samples.

How the data were processed

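Pancreatic islets of wild-type C57BL/6 mice were profiled by RNA sequencing in 2 groups of 3 libraries, one given vehicle and one given the ligand insB:9-23. Groups and replicate numbers came from the sample titles. RNA was extracted with TRIzol and libraries were made with a KAPA stranded RNA-Seq kit, per the labels' protocols. The annotation release, the strand setting, the dose, the route and the duration of treatment are not given in the sources used here. The labels do not settle whether the mice or the isolated islets received the ligand.

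The authors deposited raw read counts per Ensembl gene, 1 table per library, per the file headers. The submitters' processing notes name HISAT, featureCounts 1.5.0-p3 and DESeq 1.8.3 with the build GRCm38, and do not say which step each served. The 6 tables hold the same 55421 gene IDs. Symbols were found for 55154 of them in GENCODE mouse release M21, which uses the same build, and IDs without a symbol held at most 0.0030% of the counts of any library. Total counts lay between 52052808 and 58880189 per library. At TMM-scaled library sizes 3 counts correspond to 0.0475 to 0.0655 CPM (counts scaled to library size). Nothing in the labels ties a library to 1 animal or 1 pool, so p-values measure the spread between these libraries, which may be technical.

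Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 17016. Libraries were scaled with TMM factors, and the quasi-likelihood F test with robust dispersion compared insB:9-23 with vehicle. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05 and no limit on the fold. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. CPM values of single genes use TMM-scaled library sizes, while shares of marker lists use the total counts. Where every library of a group held 0 counts, the fold is a lower bound against 3 counts per library.

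A total of 45 gene lists for islet, exocrine, vascular, stromal and immune cell types and for pathways was fixed before the data were examined, as were the tests and the alternatives. Lists with at least 4 tested members (41 lists) were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The text names genes by a rule: up to 12 genes per direction with the largest change past the threshold, of those with a symbol that is not a predicted-gene or clone name, a mean of at least 1 CPM and groups that do not overlap; the 6 most abundant changed genes; the 3 members with the smallest p in each list that camera called; and 16 fixed genes. A gene that the rule takes is not reported here. Genes named outside this rule are marked as chosen after their values were seen.

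The tests were checked on simulated data for the comparison of insB:9-23 with vehicle, drawn from the real means, library sizes and dispersions, with 200 changed genes among 16479 tested. The edgeR test recovered 56 of 100 genes changed 4-fold and 8 of 100 changed 2-fold, with 5 false calls among 73. The other 4 calls were genes of a list of 15 shifted 2-fold. That list was called, and 0 of 44 unshifted lists were. With no gene changed the edgeR test called 3 genes. Independent draws for each gene cannot show how camera behaves when genes vary together.

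Alternatives were other scalings (RLE, upper quartile, library totals alone), DESeq2 1.42.0, limma-voom with and without sample weights, other filters on low counts, protein-coding genes only, other thresholds, the replicate number as a block, and each library left out in turn. After the data were seen, 5 more were added: leaving out genes that were 0 in some libraries and at least 5 CPM in others, leaving out single-exon genes, a covariate for the acinar marker level, insB:9-23 replicate 1 alone against vehicle, and the fry test for change in either direction. Libraries of 1 group were compared by a chi-square test of their counts, which gave a statistic of 87.1 to 270.4 per degree of freedom, so no library was a repeat deposit of another.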

Results

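The data were gene counts from 6 islet RNA-seq libraries, 3 from the vehicle group and 3 from the insB:9-23 group. The name insB:9-23 is that used for a fragment of the insulin B chain, a known target of islet autoimmunity. The question, as the study's title puts it, was on which genes and pathways of the islet the ligand acts. Total counts were 58407338, 58880189 and 52052808 in vehicle replicates 1 to 3, and 58445046, 53805531 and 56868559 in insB:9-23 replicates 1 to 3. Values below are means ± SD in CPM over n = 3 libraries per group unless stated otherwise.

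The libraries held islet RNA together with much exocrine RNA. Ins2 and Ins1, the mouse insulin genes, reached 65049 ± 5547 and 38629 ± 1983 CPM in the vehicle group. Among acinar enzymes, Cpa1, a digestive carboxypeptidase, was at 12346 ± 1246 CPM. The 26 acinar marker genes took 16.8%, 18.4% and 19.6% of all counts in the vehicle libraries and 21%, 18.5% and 28.4% in insB:9-23 replicates 1 to 3. Beta cell markers took 9.55% in insB:9-23 replicate 3 and 11.9% to 13.8% in the other 5 libraries. B and plasma cell markers took 0.0170% of counts in insB:9-23 replicate 2 and at most 0.0061% elsewhere. T and NK cell markers took 0.0038% in that library and at most 0.00095% elsewhere. The 5 Amy2a genes are near-identical amylase copies whose reads the counting could split, so they were not read singly. Together they took 9.03%, 10.2% and 10.6% of counts in vehicle replicates 1 to 3. In insB:9-23 replicates 1 to 3 they took 11.2%, 10.2% and 15.9%. The 26 acinar marker genes do not include them, so the acinar shares above leave them out.

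**Figure D1:**
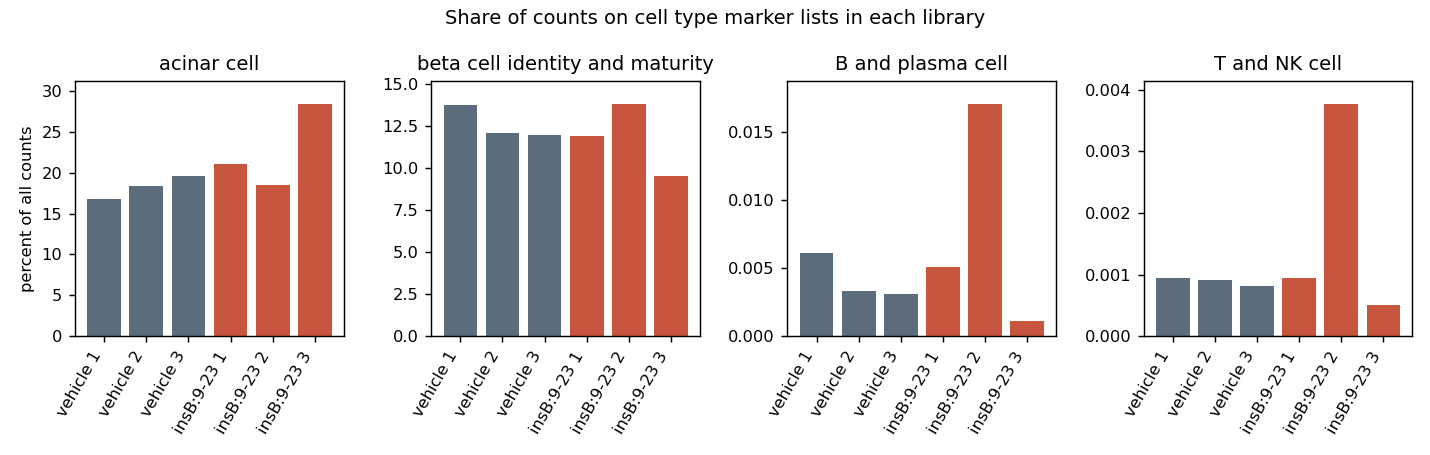
Bars give the percent of all counts (y axis, linear from 0) on 4 cell type marker lists in each library (x axis), with vehicle in grey and insB:9-23 in red. The acinar share is highest in insB:9-23 replicate 3 (28.4%), and the B and plasma cell share is highest in insB:9-23 replicate 2 (0.0170%).

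With both groups pooled, libraries of the same group were about as alike as libraries of different groups (median Pearson's correlation 0.927 for each). The vehicle pairs of replicates 1 and 2 (0.938) and 2 and 3 (0.933) lay above every pair across groups, and that of 1 and 3 (0.928) did not. The insB:9-23 pairs lay between 0.921 and 0.926. Pearson's correlation of log2 CPM across the 17016 genes lay between 0.921 and 0.938 within groups and between 0.925 and 0.931 across groups. The first 5 principal components held 22.3%, 21.1%, 20.4%, 19.5% and 16.7% of the variance, so no axis dominated. Genes are not independent replicates, and these values describe the libraries only.

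Between the groups, 14 of 17016 genes passed the edgeR test, 5 higher and 9 lower in the insB:9-23 group. In the other splits of these 6 libraries into 3 and 3, which mix the groups, edgeR called 4 to 15 genes (median 9). The strongest decreases were in Hist1h1c, a linker histone gene, and Galnt4, which starts O-linked glycosylation, both without a single count in the treated libraries. Both have a single exon, and 96 of the 124 single-exon protein-coding genes that reached 5 CPM in some library were at 0 in another. Cplx2, a complexin of the exocytosis machinery, fell from 472 ± 11 to 68.6 ± 20.2 CPM. Sort1, the sorting receptor sortilin, fell from 209 ± 24.7 to 75.7 ± 3.34 CPM. Among the increases, Smim14, a small membrane protein gene, rose from 69.5 ± 4.44 to 193 ± 8.72 CPM, and Tubb2a, a beta-tubulin, rose from 15.2 ± 0.571 to 43.9 ± 3.00 CPM. At an unadjusted p below 0.05 there were 944 genes. DESeq2 called 106 genes, which included the 14 called by edgeR. In the splits that mix the groups it called 60 to 89 genes (median 74), so a call by DESeq2 alone carries little weight.

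Of the 9 genes that were lower, 3 had 0 counts in all 3 insB:9-23 libraries. Hist1h1c stood at 113 ± 6.63 CPM in the vehicle group (6337 to 7157 counts), which makes it at least 1984-fold lower after insB:9-23 (edgeR adjusted p = 0.0014). Galnt4, at 33.0 ± 3.37 CPM in the vehicle group, was at least 581-fold lower (edgeR adjusted p = 0.0025). Nhlrc1, which encodes the ubiquitin ligase malin, was at 3.24 ± 0.124 CPM and at least 57.2-fold lower (edgeR adjusted p = 0.032). These 3 genes have 1 exon each.

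The other 6 had counts in every library. Tmx4, a thioredoxin-related membrane protein of the endoplasmic reticulum, fell by 3.13 ± 0.13 on the log2 scale (SE; edgeR adjusted p = 0.0014), from 155 ± 4.79 to 17.7 ± 2.82 CPM. Irgq, an immunity-related GTPase family gene, fell by 2.84 ± 0.21 (SE; adjusted p = 0.017), from 55.8 ± 2.23 to 7.77 ± 2.01 CPM. On the same scale Cplx2 fell by 2.78 ± 0.23 (SE; adjusted p = 0.034) and Sort1 fell by 1.46 ± 0.10 (SE; adjusted p = 0.011). Nsun3, a methyltransferase of a mitochondrial tRNA, fell by 1.81 ± 0.12 (SE; adjusted p = 0.011), and Uqcrfs1, the Rieske protein of respiratory complex III, fell by 1.51 ± 0.13 (SE; adjusted p = 0.035).

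Of the 5 genes that were higher, Lyrm9, a LYR-motif gene, rose by 2.63 ± 0.10 on the log2 scale (SE; edgeR adjusted p = 0.0014), from 6.28 ± 0.442 to 39.0 ± 2.62 CPM. Tubb2a rose by 1.53 ± 0.09 (SE; adjusted p = 0.0044) and Smim14 by 1.47 ± 0.07 (SE; adjusted p = 0.0025). Coa4, an assembly factor of cytochrome c oxidase, had 1, 1 and 2 counts in the vehicle libraries and 362, 333 and 259 in the insB:9-23 libraries (edgeR adjusted p = 0.0017). Gm15710, a processed pseudogene inside the gene Uso1, had 0 counts in the vehicle libraries and 126 ± 11.8 CPM after insB:9-23, at least 2494-fold higher (edgeR adjusted p = 0.0014). Its parent gene could share its reads, so its count is uncertain.

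**Figure D2:**
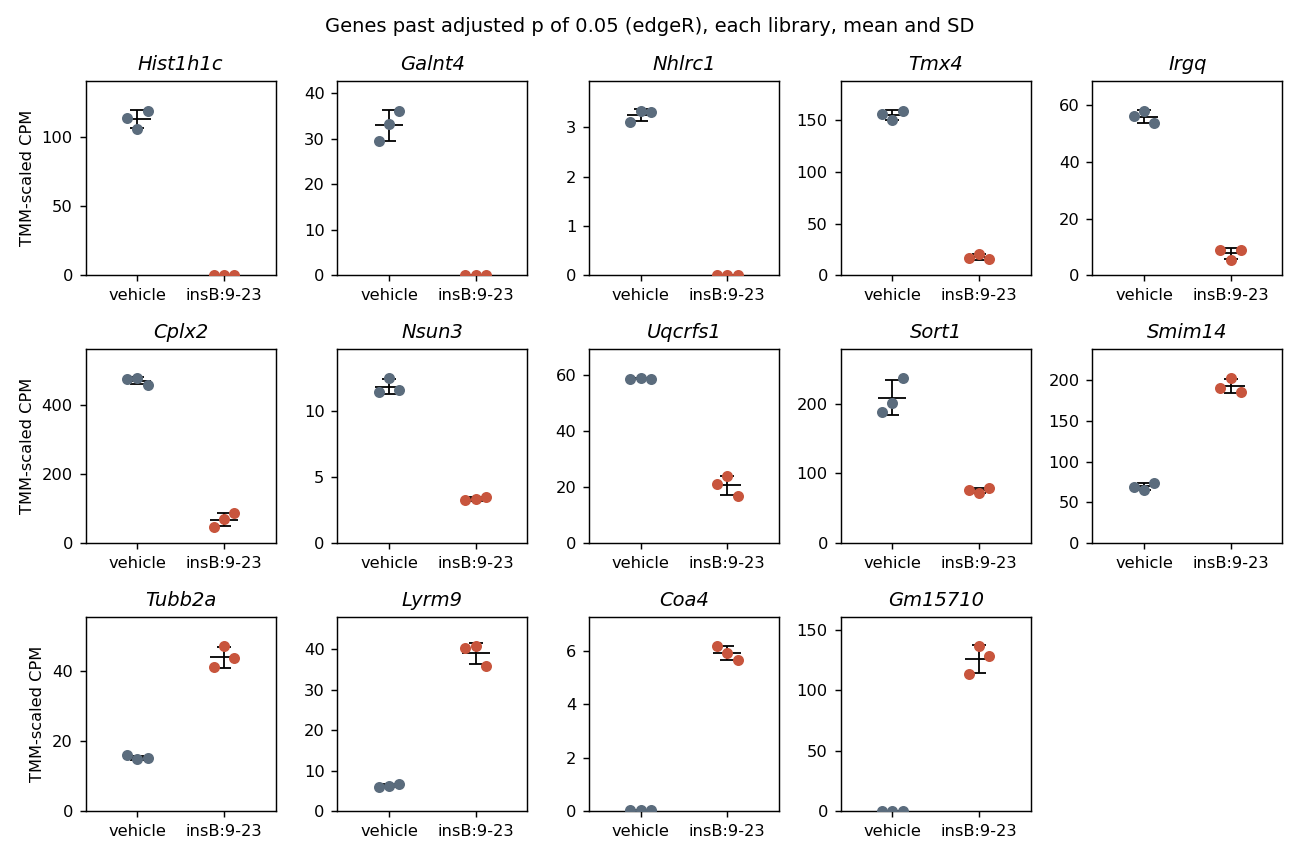
Each panel shows 1 of the 14 genes that passed the edgeR test, with the level in TMM-scaled CPM (y axis, linear from 0) in each vehicle (grey) and insB:9-23 (red) library; dashes and bars are the mean and SD of n = 3. Hist1h1c, Galnt4 and Nhlrc1 are at 0 in all insB:9-23 libraries, and Gm15710 is at 0 in all vehicle libraries.

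On GRCm38 with GENCODE M21, Tubb2a (34074274 to 34078007), Uqcrfs1 (30540308 to 30545362), Hist1h1c (23738808 to 23740367), Nhlrc1 (47012557 to 47014850) and Cplx2 (54371349 to 54383917) lie on chromosome 13. Chromosome 7 holds Coa4 (100537071 to 100540369) and Irgq (24530689 to 24538600), and chromosome 5 holds Smim14 (65446844 to 65537184) and Gm15710 (92140294 to 92140929). Lyrm9 is on chromosome 11 (78826584 to 78846870), Galnt4 on chromosome 10 (99108159 to 99113247), Tmx4 on chromosome 2 (134594185 to 134644145), Nsun3 on chromosome 16 (62732444 to 62786818) and Sort1 on chromosome 3 (108284082 to 108361511).

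Among all genes, 262 had 0 counts in 1 or more libraries and at least 5 CPM in another, 189 of them single-exon genes, and 3 of the 14 changed genes (Hist1h1c, Galnt4, Gm15710) are among these all-or-none genes. Coa4, Lyrm9, Tubb2a, Smim14, Gm15710, Tmx4, Hist1h1c and Galnt4 passed the edgeR test without each library in turn. Nhlrc1 and Irgq missed it without any 1 vehicle library (adjusted p of 0.16 to 0.20 and 0.063 to 0.073), and Irgq without insB:9-23 replicate 3 (0.054). Cplx2 and Uqcrfs1 missed it without any 1 vehicle library (0.11 to 0.13 and 0.12 to 0.13), and without insB:9-23 replicate 2 (Cplx2, 0.19) or replicate 1 (Uqcrfs1, 0.14). Nsun3 missed it without vehicle replicate 2 (0.061) or 3 (0.057) or insB:9-23 replicate 2 (0.055), and Sort1 without vehicle replicate 2 (0.054) or insB:9-23 replicate 1 (0.057) or 2 (0.072). The count was 23 without vehicle replicate 1 (14 higher, 9 lower), 25 without insB:9-23 replicate 1 (8 and 17) and 26 without insB:9-23 replicate 3 (8 and 18). Higher genes also outnumbered lower ones without vehicle replicate 2 (10 and 6) or 3 (13 and 5). The count was 7 with the acinar marker level as a covariate. That covariate ended the calls of Tubb2a (edgeR adjusted p = 0.051), Sort1 (0.069), Uqcrfs1 (0.082), Irgq (0.10), Nsun3 (0.11), Cplx2 (0.20) and Nhlrc1 (0.33). Log2 folds under it were 1.57 ± 0.11 for Tubb2a, -1.56 ± 0.12 for Sort1, -1.32 ± 0.10 for Uqcrfs1, -3.07 ± 0.26 for Irgq, -1.86 ± 0.16 for Nsun3 and -2.99 ± 0.28 for Cplx2 (SE), and of these only that of Uqcrfs1 was smaller in size than without it. Library totals alone ended those of Tubb2a and Smim14 (both 0.055) and Uqcrfs1 (0.12), and insB:9-23 replicate 1 alone those of Tubb2a (0.051), Gm15710 (0.056), Nsun3 (0.088) and Sort1 (0.13).

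The hormone genes of the islet did not pass the test. Ins2 was at 69956 ± 7059 CPM and Ins1 at 38880 ± 758 CPM after insB:9-23, with log2 fold changes of 0.10 ± 0.14 and 0.01 ± 0.10 (SE; edgeR adjusted p = 0.93 and 0.99). Gcg, encoding glucagon, was at 20916 ± 1681 in vehicle and 19932 ± 2765 CPM after the ligand (adjusted p = 0.96). Sst, encoding somatostatin, was at 2420 ± 36.0 and 2426 ± 173 CPM (adjusted p = 0.99), and Iapp, encoding amylin, at 12452 ± 752 and 11291 ± 1015 CPM (adjusted p = 0.90). Ppy, encoding pancreatic polypeptide, was at 563 ± 70.0 and 447 ± 40.4 CPM (adjusted p = 0.88). None of the 15 measured beta cell genes passed the edgeR test, and 1 was lower at an unadjusted p below 0.05. The list had a median log2 fold of -0.10 (camera adjusted p = 0.34). The alpha cell list (11 genes, 0.10, adjusted p = 0.48), delta cell list (6 genes, -0.00, adjusted p = 0.62) and PP and epsilon cell list (5 genes, -0.05, adjusted p = 0.69) were not called either, nor were the 9 autoantigen genes of type 1 diabetes (-0.03, adjusted p = 0.40).

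Antigen presentation genes did not pass the test in these libraries. H2-Aa, H2-Ab1 and H2-Eb1, the class II chains, were at 67.6 ± 9.20, 65.8 ± 6.83 and 50.7 ± 4.77 CPM in vehicle and 79.1 ± 42.2, 54.5 ± 11.3 and 63.1 ± 30.3 CPM after insB:9-23 (edgeR adjusted p = 0.95, 0.88 and 0.91). Cd74, the invariant chain, was at 163 ± 41.0 and 143 ± 55.3 CPM (adjusted p = 0.95), and Ciita, the class II transactivator, at 1.8 ± 0.284 and 1.8 ± 0.206 CPM (adjusted p = 0.999). B2m, the light chain of class I, was at 195 ± 16.2 and 188 ± 75.6 CPM (adjusted p = 0.99). The class II list had a median log2 fold of 0.16 over 14 genes (camera adjusted p = 0.92), the class I list -0.04 over 16 (0.37) and the interferon response list 0.03 over 23 (0.90). Insr, the insulin receptor, was at 53.8 ± 9.50 and 53.7 ± 17.7 CPM (edgeR adjusted p = 0.999), and the insulin receptor signalling list had a median of -0.00 over 18 genes (camera adjusted p = 0.91). Irs2, an insulin receptor substrate of that list, chosen after its values were seen, was at 26.4 ± 3.01 and 40.2 ± 3.15 CPM. It was the 1 member that passed when adjusted over the list alone (edgeR adjusted p = 0.032), against 0 over all genes (edgeR adjusted p = 0.50).

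As groups, 13 of 41 tested lists were called by camera with a preset correlation of 0.01, 10 higher and 3 lower. With an estimated correlation, 0 of 41 lists were called, although 2 lists had an unadjusted p below 0.05. With fry, which tests for change on balance in 1 direction, 0 were called too, although 5 lists had an unadjusted p below 0.05. The fry test for change in either direction, chosen after the data were seen, called 6 of 41 lists, those of exocytosis (adjusted p = 5.4e-05), immediate-early (0.0024), nuclear oxidative phosphorylation (0.0024), clock (0.0030), fatty acid (0.010) and hypoxia genes (0.020). A few strongly changed members can carry that test. The exocytosis list holds Cplx2 and the nuclear oxidative phosphorylation list holds Uqcrfs1, and the test was not run without them. Among the members of the 13 lists called by camera, only Cplx2 passed the edgeR test over all genes. Camera tests whether a list moves relative to other genes, with 0.009 as the median log2 fold over all genes. With the acinar marker level as a covariate, calls were lost for acinar (camera adjusted p = 0.62), duct (0.26), extracellular matrix (0.62), regeneration (0.15), hypoxia (0.15), heat shock (0.079) and immediate-early genes (0.059). Under it 13 lists were called, with only 6 of the original 13 among them. Medians of the B and plasma cell and T and NK cell lists rose to 2.65 and 1.54 (camera adjusted p = 3.1e-13 and 2.0e-10). With insB:9-23 replicate 1 alone, calls were lost for duct (camera adjusted p = 0.11), ribosomal protein (0.12), exocytosis (0.15), heat shock (0.57), proliferation (0.72), hypoxia, extracellular matrix and T and NK cell genes (each 0.76). By library totals alone the median of all genes was -0.15, and list medians were 0.020 for regeneration, 0.054 for duct, 0.13 for immediate-early, 0.32 for acinar, -0.25 for exocytosis, -0.27 for cholesterol synthesis and -0.32 for extracellular matrix genes.

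Cytosolic ribosomal protein genes stood higher together. All 26 measured members had a fold above 0, with a median log2 fold of 0.21 (camera adjusted p = 1.3e-09; adjusted p = 0.64 with an estimated correlation), and 15 had an unadjusted p below 0.05. Rplp0 was at 474 ± 7.94 CPM in vehicle and 561 ± 35.1 after insB:9-23, Rpl14 at 113 ± 8.69 and 141 ± 9.67, and Rps3 at 236 ± 12 and 281 ± 16.8, each with an edgeR adjusted p of 0.88. By library totals alone the median was 0.06, against a median of -0.15 over all genes.

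Immediate-early genes, which respond quickly to stimulation, were higher as a list. Of 18 members 16 had a fold above 0, with a median log2 fold of 0.28 (camera adjusted p = 0.0023; adjusted p = 0.60 with an estimated correlation). The median was 0.17 with all-or-none genes left out (camera adjusted p = 0.0032). Fosb was at 425 ± 25.7 and 626 ± 38.8 CPM, Nr4a1 at 96.4 ± 4.31 and 142 ± 12.5 CPM, and Egr1 at 503 ± 30.6 and 665 ± 24.7 CPM, with edgeR adjusted p of 0.18, 0.23 and 0.34. DESeq2 called all 3 (adjusted p = 0.00035, 0.0020 and 0.025), but it also called 60 to 89 genes in splits that mix the groups. Adjusted over the list alone, 3 members (Fosb, Nr4a1 and Egr1) were higher and 1 was lower, against 0 over all genes. The lower one, Egr3, chosen after its values were seen, was at 2.66 ± 1.20 and 0.157 ± 0.127 CPM.

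The stimulus-secretion coupling and exocytosis list was lower, with 16 of 18 members below 0 and a median log2 fold of -0.11 (camera adjusted p = 0.0023; adjusted p = 0.60 with an estimated correlation). Beside Cplx2, which passed over all genes, Syt7, a calcium sensor of insulin granules, was at 160 ± 11 CPM in vehicle and 105.9 ± 16.6 after insB:9-23. It passed when adjusted over the list alone (edgeR adjusted p = 0.028; over all genes 0.65), and over all genes with DESeq2 (adjusted p = 0.042). Sytl4, encoding granuphilin, was at 319 ± 12.9 and 283 ± 7.06 CPM (edgeR adjusted p = 0.88). Adjusted over the list alone, 2 members were lower and 0 were higher. Without vehicle replicate 2 the median was -0.065 (camera adjusted p = 0.037).

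Cholesterol synthesis genes were lower as a list, with 16 of 20 members below 0 and a median log2 fold of -0.11 (camera adjusted p = 0.011; adjusted p = 0.60 with an estimated correlation). Stard4, a cholesterol transfer protein, was at 9.20 ± 2.5 and 4.59 ± 0.540 CPM, and Lss, lanosterol synthase, at 27.0 ± 1.12 and 22.1 ± 0.330 CPM (edgeR adjusted p = 0.83 and 0.88). The call was lost without vehicle replicate 3 (camera adjusted p = 0.077) or insB:9-23 replicate 1 (0.099), and the median was -0.066 without the latter. The extracellular matrix and TGF-beta target list had 13 of 14 members below 0 and a median of -0.21 (camera adjusted p = 0.011; adjusted p = 0.64 with an estimated correlation). Col4a1, a basement membrane collagen, was at 157 ± 8.47 and 136 ± 4.28 CPM, Tgfbi at 10.4 ± 1.58 and 8.21 ± 1.19 CPM, and Lox, lysyl oxidase, at 0.445 ± 0.355 and 0.146 ± 0.081 CPM (each edgeR adjusted p = 0.88). The call was lost without vehicle replicate 1 (camera adjusted p = 0.38), vehicle replicate 3 (0.066), insB:9-23 replicate 2 (0.16) or insB:9-23 replicate 3 (0.25), and without the last the median was -0.10.

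Exocrine markers were higher as lists, and the acinar share was highest in insB:9-23 replicate 3. Of 26 acinar genes 25 had a fold above 0, with a median log2 fold of 0.52 (camera adjusted p = 2.0e-08; adjusted p = 0.72 with an estimated correlation) and none past the edgeR test. Cpa1 was at 16417 ± 5696 CPM after insB:9-23 (adjusted p = 0.88), Try5, a trypsin gene with close paralogs, at 7432 ± 775 and 11968 ± 4867 CPM, Ptf1a, an acinar transcription factor, at 2.89 ± 0.035 and 4.70 ± 1.88 CPM, and Rnase1 at 1.82 ± 0.455 and 3.46 ± 1.05 CPM (each edgeR adjusted p = 0.88). Without insB:9-23 replicate 3 the median was 0.16 (camera adjusted p = 0.011). The duct cell list had 10 of 11 members above 0 and a median of 0.22 (camera adjusted p = 0.0073; adjusted p = 0.60 with an estimated correlation), and missed the threshold without that library (camera adjusted p = 0.053). Its median was 0.35 without vehicle replicate 3. Krt8 was at 134 ± 12.5 and 162 ± 2.91 CPM, Spp1, osteopontin, at 27.0 ± 5.59 and 39.6 ± 4.27 CPM, and Muc1 at 43.5 ± 4.95 and 67.0 ± 21.8 CPM (each edgeR adjusted p = 0.88).

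Regeneration and dedifferentiation genes were higher as a list, 10 of 12 above 0 with a median log2 fold of 0.21 (camera adjusted p = 0.039; adjusted p = 0.60 with an estimated correlation). Reg3a and Reg3b, secreted lectins of stressed pancreas, were at 159 ± 22.3 and 393 ± 70.2 CPM in vehicle and 368 ± 154 and 767 ± 329 CPM after insB:9-23, and Neurog3, the endocrine progenitor factor, at 0.176 ± 0.067 and 2.26 ± 1.81 CPM (each edgeR adjusted p = 0.88). The call was lost without each library in turn other than insB:9-23 replicate 2 (camera adjusted p of 0.051 to 0.23), where the median was 0.34. It was also lost with 1 CPM required in 3 libraries (0.11). DESeq2 called Reg3a and Neurog3 (adjusted p = 0.014 and 0.010). The acinar share was highest in insB:9-23 replicate 3 (28.4%).

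The hypoxia response list (9 of 12 above 0) had a median of 0.11 (camera adjusted p = 0.019; adjusted p = 0.64 with an estimated correlation). Ddit4, a stress-induced mTORC1 inhibitor, was at 41.8 ± 2.44 and 62.9 ± 2.07 CPM (edgeR adjusted p = 0.15). It passed when adjusted over the list alone (edgeR adjusted p = 0.0025), and over all genes with DESeq2 (adjusted p = 8.2e-05). Ndrg1 was at 141 ± 3.48 and 162 ± 10.2 CPM and Egln1 at 24.1 ± 14.4 and 40.7 ± 2.74 CPM (both edgeR adjusted p = 0.88), and Egln1 passed without vehicle replicate 3 (0.045). The heat shock list (10 of 11 above 0) had a median of 0.13 (camera adjusted p = 0.044; adjusted p = 0.60 with an estimated correlation), with Hsph1 at 149 ± 11.9 and 172 ± 2.74 CPM, Dnajb1 at 227 ± 15.9 and 310.1 ± 73.4 CPM and Hspa8 at 919 ± 72.2 and 1065 ± 93.6 CPM (each edgeR adjusted p = 0.88). By library totals alone the medians of the hypoxia and heat shock lists turned to -0.04 and -0.0074, and neither was called. The hypoxia call was lost without vehicle replicate 2, insB:9-23 replicate 2 or insB:9-23 replicate 3 (camera adjusted p = 0.19, 0.091 and 0.13), and the heat shock call without each library other than vehicle replicate 2 (0.077 to 0.97). Without 1 library the hypoxia median ranged from 0.053 (vehicle replicate 2) to 0.25 (vehicle replicate 1), and was 0.20 without insB:9-23 replicate 1. The heat shock median was 0.068 without vehicle replicate 1. Hspa1b, a listed gene chosen after its values were seen, was filtered out, with counts in vehicle replicates 2 and 3 only. Over all 12 listed genes the summed level by library totals was 3196, 4606 and 4394 CPM in vehicle replicates 1 to 3. It was 3209, 3763 and 2574 CPM in insB:9-23 replicates 1 to 3. These sums hold Hspa1b, at 1328 and 1225 CPM in vehicle replicates 2 and 3 and at 0 elsewhere. They also leave out the TMM factors (0.806 in insB:9-23 replicate 3). They therefore cannot tell whether the other members were higher or lower together. The proliferation list (16 of 20 above 0) had a median of 0.25 (camera adjusted p = 0.018; adjusted p = 0.72 with an estimated correlation). Mki67 was at 11.7 ± 0.603 and 14.8 ± 2.70 CPM, Cdk1 at 1.99 ± 0.519 and 3.08 ± 0.657 CPM and Ccnb2 at 1.33 ± 0.113 and 1.93 ± 0.255 CPM (each edgeR adjusted p = 0.88). The summed level of the list was highest in insB:9-23 replicate 2 (149 CPM, and 98.2 to 121 CPM elsewhere), where B and plasma cell and T and NK cell markers were highest too. The call was lost without that library (median 0.14, camera adjusted p = 0.27), without vehicle replicate 1 (0.16), without vehicle replicate 2 (0.074) and by library totals alone (0.053).

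Lymphocyte markers were higher as lists, and most members were highest in insB:9-23 replicate 2. The T and NK cell list had 18 of 19 members above 0 and a median log2 fold of 1.09 (camera adjusted p = 0.018; adjusted p = 0.80 with an estimated correlation), and the B and plasma cell list 10 of 12 and 1.43 (camera adjusted p = 0.044; adjusted p = 0.80 with an estimated correlation). Without insB:9-23 replicate 2 the medians were -0.30 and 0.16 (camera adjusted p = 0.46 and 0.997). Without vehicle replicate 3 the calls were lost too (0.077 and 0.28), and that of B and plasma cell genes also without vehicle replicate 2 (0.17) or insB:9-23 replicate 1 (0.086). With insB:9-23 replicate 1 alone the B and plasma cell list was called (median 0.57, camera adjusted p = 0.018) and the T and NK cell list was not (0.23, 0.76). Levels were low. Ms4a1, encoding CD20, was at 0.425 ± 0.229 and 7.56 ± 11 CPM, Cd79b at 0.202 ± 0.066 and 4.13 ± 6.13 CPM, Ighd at 0.305 ± 0.172 and 1.78 ± 1.73 CPM, Cd3g at 0.277 ± 0.057 and 1.72 ± 1.93 CPM, Cd28 at 0.173 ± 0.139 and 0.842 ± 0.792 CPM, and Il7r at 0.473 ± 0.038 and 1.01 ± 0.344 CPM, none past the edgeR test (each adjusted p = 0.88). DESeq2 called Cd79b (adjusted p = 0.039). Ptprc, encoding CD45, was at 10.6 ± 0.491 and 16.2 ± 15.5 CPM (edgeR adjusted p = 0.92), and Pecam1, an endothelial marker, at 40.7 ± 2.60 and 41.9 ± 9.39 CPM (adjusted p = 0.98).

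**Figure D3:**
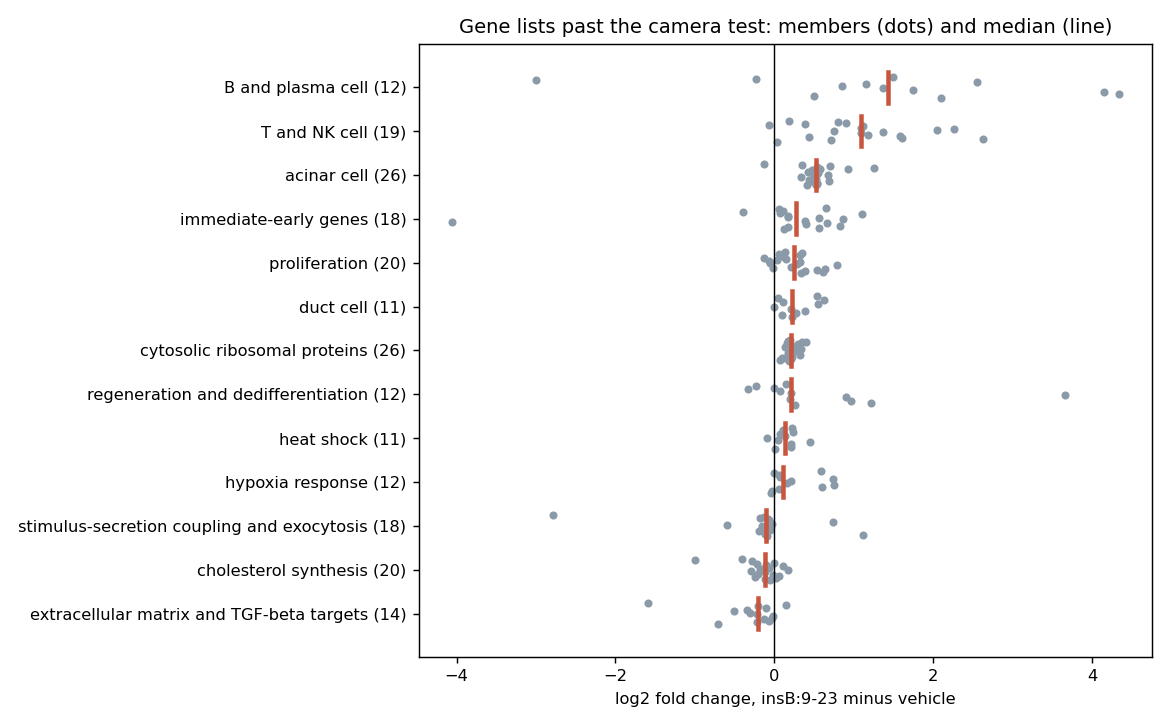
Dots give the log2 fold change, insB:9-23 minus vehicle (x axis), of each measured member of the 13 lists called by camera with a preset correlation (y axis, number of members in brackets); red lines are list medians. Medians run from -0.21 for extracellular matrix genes to 1.43 for B and plasma cell genes, and 0 of the 13 were called with an estimated correlation.

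The other lists were not called by camera. Of cell type lists, Schwann cell and neuron genes had a median log2 fold of -0.23 (camera adjusted p = 0.053), erythroid genes -0.47 (0.089), endothelial genes -0.05 (0.40), dendritic cell genes 0.07 (0.56), macrophage and myeloid genes -0.09 (0.56) and stellate cell, pericyte and fibroblast genes -0.05 (0.90). Of metabolic and stress lists, beta cell disallowed genes had a median of 0.36 (0.072), granule and prohormone processing genes -0.06 (0.089), apoptosis and p53 targets 0.09 (0.13), autophagy and lysosome genes 0.03 (0.73), fatty acid genes -0.01 (0.90), nuclear oxidative phosphorylation genes 0.05 (0.91), antioxidant genes 0.04 (0.96), glycolysis genes -0.05 (0.97) and unfolded protein response genes 0.04 (0.97). In the nuclear oxidative phosphorylation list 9 of 26 members had a fold below 0, and 1 of them, Uqcrfs1, passed the edgeR test. Of immune and timing lists, T-cell receptor signalling genes had a median of 0.61 (0.11), NF-kB targets and cytokines 0.19 (0.24), complement and innate sensing genes 0.27 (0.40) and circadian clock genes 0.06 (0.40). The neutrophil, adipocyte, mitochondrially encoded and histone lists had 1, 1, 3 and 3 tested members and were too small to test.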

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

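The settings that leave out all-or-none or single-exon genes, use the acinar marker level, use insB:9-23 replicate 1 alone, or use fry for change in either direction were chosen after the data were seen. The count of 14 changed genes stayed within 1.5 times (10 to 19) under the other scalings, limma-voom, other filters, other thresholds and both gene exclusions. DESeq2 called 106 genes, 54 higher and 52 lower (the cause was not tested). The acinar covariate left 7, and insB:9-23 replicate 1 alone gave 70, where that library is assumed to vary like the vehicle group. Leaving out 1 library gave 16 to 26 genes, with 8 to 13 of the original 14 among them (the cause was not tested). With the replicate number as a block, edgeR called 0 genes (605 at an unadjusted p below 0.05) and 10 lists, those of T and NK cell, B and plasma cell and heat shock genes being lost. Same-numbered libraries deviated with correlations of -0.035, -0.064 and -0.025 and none went best with its own number, so the numbers were not read as pairs. Over the 68 named genes and their 1343 alternative values, 49 lost a call and 9 gained one. All 49 losses fell on the 14 called genes, the only ones with a call to lose. Those genes had 17 to 20 alternative values each, so 1343 is not the base for the losses. Uqcrfs1 kept its call in 13 of 20, and Coa4 in 19 of 20. The count of reversals was 0, but turns of sign in genes uncalled under both settings were not counted as reversals. Coa4, Lyrm9, Tmx4, Hist1h1c and Galnt4 missed the threshold only under the block, of the settings that tested them. The 13 called lists fell to 0 with an estimated correlation (2 at an unadjusted p below 0.05) and to 0 with fry (5). The fry test for change in either direction, which asks another question, called 6 lists, 3 of the 13 among them. Leaving out 1 library gave 7 to 13 lists, and insB:9-23 replicate 1 alone gave 7. The direction of the camera test turned for the acinar list with the acinar covariate (median log2 fold -0.013), which is built from the list itself, and for extracellular matrix genes with insB:9-23 replicate 1 alone (-0.033; the cause was not tested). It turned for T and NK cell genes without insB:9-23 replicate 2 (-0.30; range without 1 library -0.30 to 1.30), and for B and plasma cell genes without that library (0.16; range 0.16 to 1.91) and with 1 CPM required in 3 libraries (0.15), which left 4 members; the median stayed above 0 there. T and NK cell genes had too few members left for a test with that filter. It turned for heat shock genes without vehicle replicate 1 (0.068, with a range of 0.068 to 0.18), where 12 rather than 11 members were tested, Hspa1b among them. Library totals alone moved the median of all genes from 0.0087 to -0.15. At TMM-scaled library sizes, 3 counts were at most 0.0655 CPM.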

Other observations

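Chosen after the results were seen were the tests of exon structure and of zeros parted by treatment, the regroupings counted by edgeR, the reading of the acinar list without insB:9-23 replicate 3 as a test of its source, insB:9-23 replicate 1 alone, and the tests of where lymphocyte markers were highest and of lymphocyte entry. Clock genes were not called as a list by camera, though fry for change in either direction, also chosen after, called them (adjusted p = 0.0030), and adjusted over the list alone 3 of 15 members were higher and 1 was lower, against 0 over all genes. Nr1d1, encoding REV-ERB alpha, was at 38.6 ± 3.92 CPM in vehicle and 58.7 ± 4.69 CPM after insB:9-23 (means ± SD, n = 3). Per1 was at 43.0 ± 6.09 and 62.3 ± 7.55 CPM, Nr1d2 at 110 ± 7.59 and 137 ± 12.4 CPM, and Cry1 at 13.3 ± 1.92 and 8.15 ± 0.953 CPM. None passed over all genes (edgeR adjusted p = 0.38, 0.88, 0.88 and 0.79). The labels give no time of collection. These genes were chosen after their values were seen.

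Several genes that are abundant in most cells were nearly missing, or present in some libraries only. Gapdh, a glycolytic enzyme, was at 0.034 to 9.20 CPM, while Rplp0 was at 468 CPM or more in each library. The 13 protein-coding genes of mitochondrial DNA took 2.9e-05% to 0.43% of counts. In 3 libraries most came from mt-Cytb, cytochrome b, at 4341, 4084 and 2971 CPM in vehicle replicate 3 and insB:9-23 replicates 2 and 3 and at most 0.017 CPM in the others. Pcbp1 was at 145 and 114 CPM in insB:9-23 replicates 1 and 3 and at 0 elsewhere. Hspa1b was at 1328 and 1225 CPM in vehicle replicates 2 and 3 and at 0 elsewhere, while its paralog Hspa1a held 825 to 1181 CPM. Gnai3, a gene of 9 exons, was at 37.0 and 39.6 CPM in insB:9-23 replicates 1 and 3 and at 101 to 111 CPM elsewhere. These genes were chosen after their values were seen, and their CPM values use plain library totals, except for Rplp0.

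In all, 262 genes had 0 counts in 1 or more libraries and at least 5 CPM in another. A copy at 95% identity over 80% of the length was found for only 9.38% of the 96 single-exon protein-coding genes searched. For these 96 genes this argues against reads moved to near-identical copies of that length. Shorter matching stretches did not count. The rest of the 262 genes, the processed pseudogene Gm15710 among them, were not searched, so for them this stays open. Switching by insB:9-23 as the source of the whole pattern is argued against by the regroupings. The zeros of 3 such genes parted the libraries by treatment, and those of 0 to 8 (median 3) by the other splits. A quantification that keeps or drops whole genes by exon structure stays open: 72.1% of the 262 genes have a single exon, against 0.596% of 10906 other genes that reached 5 CPM (Fisher's exact test, two-sided, p = 5.0e-288, though genes are not independent). As a hypothesis, such a step may also lie behind the called single-exon genes Hist1h1c, Galnt4, Nhlrc1 and Gm15710, and steps in genes with more exons (Gnai3, or Coa4 with 2) leave the other calls open to a like doubt.

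The acinar list was higher in the insB:9-23 group by a median log2 fold of 0.52. More acinar RNA in insB:9-23 replicate 3 alone may account for part of this, as a hypothesis, since the median was 0.16 without that library. With insB:9-23 replicate 1 alone against vehicle the median was 0.28. Cpa1 was at 22868 CPM in insB:9-23 replicate 3, 14299 CPM in replicate 1 and 12084 CPM in replicate 2, and at 10989 to 13438 CPM in vehicle. A change of exocrine genes with treatment stays open, as camera still called the list without that library (adjusted p = 0.011; 1.6e-15 to 0.011 over leaving out each library). Over all libraries the call was lost with an estimated correlation (adjusted p = 0.72) and with fry (adjusted p = 0.64).

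The lymphocyte lists were higher in the insB:9-23 group, and 93.5% of their 31 measured members were highest in insB:9-23 replicate 2. Lymphoid cells in that library are a candidate source, as a hypothesis, with Ms4a1 at 20.2 CPM there. Ms4a1 was at 2.20 CPM in insB:9-23 replicate 1 and at most 0.57 CPM elsewhere. Of insB:9-23 replicate 1 the values are mixed, since the B and plasma cell list was called with it alone against vehicle (camera adjusted p = 0.018, preset correlation, an arm of 1 library), yet its summed level of 50.7 CPM lay below the 61.1 CPM of vehicle replicate 1. Entry in each treated sample is not settled for B and plasma cells. Summed levels of 2 of the 3 insB:9-23 libraries lay at or below the highest vehicle library by library totals and with TMM. However, abundant members can dominate such sums. Ms4a1, Cd79b and Ighd, the members with the smallest p, were at 2.20, 1.09 and 1.26 CPM in insB:9-23 replicate 1. They were at most 0.57, 0.25 and 0.49 CPM in vehicle, and at 0.28, 0.11 and 0.37 CPM in insB:9-23 replicate 3. For T and NK cells 2 sums lay at or below the highest vehicle library by totals and 1 with TMM. Although the sum of insB:9-23 replicate 3 lay below each vehicle library (5.01 against 8.22 CPM or more, and 6.22 against 8.0 with TMM), this rests on 1 library. Members with the smallest p were mixed. In insB:9-23 replicates 1 to 3 Cd3g was at 0.785, 3.95 and 0.437 CPM (at most 0.337 in vehicle). Il7r was at 0.649, 1.33 and 1.05 CPM (at most 0.507). Cd28 was at 0.666, 1.71 and 0.153 CPM (at most 0.332). Entry of T and NK cells in some or all treated samples stays open. Such entry would need treatment of the mice rather than of isolated islets, which the labels do not settle, and lymphoid tissue taken along was not tested.

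The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. With edgeR the real grouping called 14 genes and the other splits 4 to 15 (median 9), so 2 of 10 splits gave as many. With DESeq2 the values were 106 and 60 to 89 (median 74). For lists called by camera they were 13 and 5 to 11 (median 7). With DESeq2 and for lists alike, 1 of 10 splits, the real one, gave as many. The share of tested genes whose groups did not overlap was 13.5% for the real grouping and 12.9% for the highest other, with 10% given by chance.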
